A study of Arabidopsis thaliana with 6 samples.

How the data were processed

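Rosette leaves of 3-week-old soil-grown plants, 5 to 6 plants per sample, were collected after 8 h of darkness and 30 min, 60 min or 2 h of light. Per the labels and the series' design text, total RNA of 2 biological experiments was pooled before labelling, 20 µg were used for the biotin-labelled target, and Affymetrix ATH1 arrays were hybridised. Pooling means that the spread between the 2 experiments is not in the values. Genotype and time of each array were taken from its title.

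The deposited values are MAS5 signals, that is intensity per probe set on a linear scale, and the submitters' processing notes name MAS5 as the software, with the version not given in the sources used here. Each array had been scaled by the authors before deposit, since the mean of its signals after trimming 2% at each end was 500.0 on every array. MAS5 subtracts mismatch signals, which makes dim values noisy, and no detection calls were used here. Of 22810 probe sets, 64 are control probe sets and were left out. No column of the table was left unused.

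Gene names came from the platform annotation supplied for the probe sets and from a RefSeq gene table of assembly GCF_000001735.4 (TAIR10.1), used for names only. In the annotation 13513 probe sets had 1 gene, 503 had several and 8794 had none and are unnamed here. Of those with 1 gene, 13436 matched the RefSeq table. The files name no genome build, so no coordinates are given.

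Signals were rescaled to a 2% trimmed mean of 500 and put on the scale log2(signal + 50). The offset makes log2 differences of dim probe sets smaller than those of the signals. A probe set entered the tests if its highest signal over the 6 arrays reached the median of all values, 185, which left 13064, of which 6928 have 1 named gene. Differences were fitted with limma 3.58.1 in R 4.3.3, with time as a factor and genotype additive, a trend in the variance prior (4.18 prior degrees of freedom) and Benjamini-Hochberg adjustment, with a threshold of 0.05. Each group had 1 array, so the residual of 2 degrees of freedom held array noise and any change of the genotype difference with time. The p-values thus measure the spread over 3 times, not over replicates of 1 time. Differences at a single time have no test. Their change with time was tested, after it had been seen, with a term for genotype by log2 minutes added to this fit, a test not tried on simulated data. Its residual of 1 degree of freedom is the departure of the genotype difference from a straight line over log2 minutes, not a spread over replicates.

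The design, the tests, the alternatives, 24 gene lists and the rule for the genes named were fixed before the data were examined. The rule took genes of a single locus: the 12 highest and 12 lowest mean differences among those past the threshold with 1 sign at all times, the 5 largest and 5 smallest differences at each time and in the change from 30 min to 2 h among probe sets whose brightest array reached the 75th percentile (591), and the 6 largest and 6 smallest changes from 30 min to 2 h. None of the latter passed, so genes at least 2-fold apart in both genotypes were taken. Up to 4 genes per list with the largest differences were added. PORB and PSBW were named outside this rule, after their values were seen. FLU was to be named in every sample and had no named probe set. Of 409 list entries, 64 had a named probe set and 58 were tested. As a consequence 9 lists of at least 3 tested genes were tested as sets, 12 had 1 or 2 genes and 3 had none. A further 21 families, defined by gene symbols, were added after the annotation had been seen and before any difference had been computed.

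Lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives, and at each time the median of a list was ranked among 10000 random lists matched on mean expression. With an estimated correlation 0 of the 9 lists kept its call. The residuals behind that estimate have only 2 degrees of freedom. The random lists drew their genes independently, so for genes that vary together the ranks are a description and not a test. Alternatives, each run for the results it applies to, were an offset of 16 or 100, quantile normalization, the deposited values without rescaling, no filter or one at the 75th percentile, a variance prior without trend, each time left out, no time in the fit, and stricter sizes of change. The test of genotype by log2 minutes was run with the other offsets, scalings, filters and variance prior, all chosen after its result had been seen. With a time left out it has no residual degree of freedom.

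The fit was tested on simulated data, 6 arrays of 13064 probe sets with 200 changed. It recovered 4.5% of those changed 2-fold, 77.6% of those changed 4-fold at every time, and 0% of those whose log2 difference grew with time from 0, and 2 unchanged probe sets were called. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.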

Results

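Transcript levels in rosette leaves of Arabidopsis thaliana were measured in 2 genotypes, the wild type Landsberg erecta (Ler) and the flu mutant, which carries the allele flu1-1 in the same ecotype. FLU is a nuclear-encoded plastid protein that holds back tetrapyrrole synthesis in the dark. Mutant plants build up protochlorophyllide, a chlorophyll precursor, during darkness, and this photosensitiser releases singlet oxygen inside the plastids when the light returns. Plants 3 weeks old, raised in continuous light, were kept dark for 8 h and sampled after 30 min, 60 min and 2 h of renewed light. Each genotype and time was measured on 1 ATH1 array, 6 arrays in all, so no value at a single time has a replicate, and the number of arrays limits the precision. None of the arrays is of plants before the renewed light. A difference already present in the dark thus cannot be told from one that arose in the light. FLU itself is not reported here, since no probe set carried its name in the annotation used. Across the probe sets, log2 signals of the flu and Ler arrays correlated with r = 0.967 at 30 min, 0.952 at 60 min and 0.915 at 2 h, against 0.973 to 0.982 among the Ler arrays and 0.937 to 0.974 among the flu arrays. These correlations are across genes, which are not independent replicates.

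The question of which transcripts differed between flu and Ler throughout the first 2 h of light was addressed with the 3 times as blocks. STZ, a C2H2 zinc finger repressor of stress responses also known as ZAT10, was higher in flu by 4.43 on the log2 scale (SE 0.16, adjusted p = 0.000542, higher at 3 of 3 times). In order of time, its signals in flu were 6741, 8279 and 6607, against 308, 283 and 267 in Ler. Among probe sets of a single named gene, AT4G29780 (4.92, SE 0.19, adjusted p = 0.000542), AT1G05575 (4.86, SE 0.35, adjusted p = 0.00176) and AT2G22880 (4.80, SE 0.26, adjusted p = 0.00104) had the largest mean differences. Their order depends on the offset, since AT2G22880 had Ler signals of 4.0, 6.0 and 3.7, near background, and with an offset of 16 the means were 5.22, 5.34 and 6.17. The calmodulin-like genes AT3G01830 (CML40) and CML37 were higher by 4.16 (SE 0.23, adjusted p = 0.00104) and 3.99 (SE 0.38, adjusted p = 0.00412). The other named genes with the largest differences were AT3G04640 (4.16), AT2G32030 (4.06), AT3G02840 (4.02), AT4G39670 (3.95), AT2G24600 (3.93) and XTH18 (3.77), a gene of the cell wall enzyme xyloglucan endotransglucosylase, with adjusted p between 0.000542 and 0.0147.

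The genes that were lower in flu at all 3 times had smaller differences. AT1G60590, a pectin lyase-like gene, was lower by a log2 difference of -2.72 (SE 0.38, adjusted p = 0.0175), with signals of 463, 227 and 92.5 in flu against 1466, 2099 and 1711 in Ler. AT2G47440 differed by -1.47 (SE 0.27, adjusted p = 0.0479), AT1G55960 by -1.44 (SE 0.15, adjusted p = 0.00573), AT5G62730 by -1.42 (SE 0.26, adjusted p = 0.0488) and AT3G14395 by -1.41 (SE 0.24, adjusted p = 0.0377). GIS, a zinc finger regulator of trichome initiation, differed by -1.11 (SE 0.17, adjusted p = 0.0278), and CRR42, needed for a chloroplast electron transport complex, by -0.99 (SE 0.18, adjusted p = 0.0488). AT5G55580 (mTERF9), of a family that acts on organelle transcripts, differed by -0.98 (SE 0.16, adjusted p = 0.0308). The remaining 4 named genes were AT5G47610 (-1.17), AT4G35320 (-1.14), AT5G42760 (-1.11) and AT5G55620 (-0.97).

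Of 13064 probe sets tested, 375 were higher and 49 lower in flu at an adjusted p under 0.05 (limma, genotype and time additive), so 88.4% of the calls were higher. With another offset, scaling, filter or variance prior, or without time in the fit, 14 to 131 were lower, and 76.5% to 95.4% of the calls were higher. All 424 had the same sign at all 3 times. The median change was 4.11-fold among the higher and 1.91-fold among the lower probe sets. At an unadjusted p under 0.05 there were 1203 higher and 1464 lower. Differences of at least 2-fold at each of the 3 times were found for 301 probe sets in the higher and 6 in the lower direction. A response that grew with time counted as noise in this test, since the residual of 2 degrees of freedom held both. Without the arrays of 60 min, 75 probe sets passed as higher and 0 as lower. Of the 12 named higher genes 10 were among them (AT4G39670 and XTH18 had adjusted p = 0.112 and 0.0617), and of the 12 named lower genes 0. Their mean differences without 60 min were close to those with it, from -2.59 to -0.87 for the 12 lower genes against -2.72 to -0.97, and 4.15 for AT4G39670 and 3.62 for XTH18. Without those of 30 min 567 were higher and 134 lower, with 12 and 9 of the named genes, and without those of 2 h 595 and 122, with all 24 of them.

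The single times were compared on 1 array of each genotype, and the genes named are the most different among brighter probe sets of a single gene. At 30 min of light these were AT4G29780 (5.04), STZ (4.25), AT2G22880 (4.12), AT3G04640 (4.02) and AT1G35210 (4.01). In the other direction psbA, the plastid gene of the D1 protein of photosystem II, had the most negative difference at -2.42, with a signal of 770 in flu against 4343 in Ler. The next were AT1G60590 (-1.56), AT1G55960 (-1.55), AT5G42760 (-1.51) and AT3G48460 (-1.47). For psbA the differences at 60 min and 2 h were 0.20 and 0.79. The flu array of 30 min had the lowest signal of the hybridisation controls, which are RNAs added before hybridisation (geometric mean 532, against 781 to 1217 on the other arrays). At 60 min AT4G29780 (5.22), AT1G05575 (5.01), AT2G22880 (4.96), AT2G24600 (4.85) and STZ (4.64) led, and AT1G60590 (-2.96), AT5G62730 (-1.90), TBL26 (-1.83), AT1G23205 (-1.83) and AT5G62140 (-1.81) stood at the low end.

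At 2 h the small heat shock protein gene AT2G29500 had a difference of 5.78, with a signal of 4419 in flu against 31.5 in Ler. At 30 min its signals were 16.4 in flu and 39.3 in Ler, both below the median signal of 185. AT1G05575 (5.75), AT4G39670 (5.64), AT2G22880 (5.32) and CML37 (5.21) were the others at the top, an order that the low Ler signals leave to the offset (6.54 for AT2G29500 and 6.75 for AT2G22880 with an offset of 16). The most negative differences were those of AT1G60590 (-3.63), AT1G13650 (signal 225 in flu against 2153 in Ler), AT5G44680 (-2.83), AT5G48490 (-2.81) and AT1G23205 (-2.63). None of the differences at a single time has a test.

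The number of probe sets at least 2-fold apart was larger at the later times. At 30 min 389 were higher and 54 lower in flu, at 60 min 799 and 188, and at 2 h 1321 and 719. Higher probe sets made up 87.8%, 81.0% and 64.8% of these. The 54 lower at 30 min depend on the setting, with 216 without a filter, 116 with an offset of 16, 25 with an offset of 100 and 27 with the stricter filter, and the share higher at 30 min was 67.8% without a filter. Between Ler arrays, 159 probe sets were at least 2-fold apart from 30 min to 60 min, 183 from 60 min to 2 h and 358 from 30 min to 2 h. Of these 64, 131 and 183 were lower at the later time, each more than the 54 lower in flu at 30 min. The median log2 difference of all tested probe sets was -0.04, -0.08 and -0.20 at the 3 times, so that a list at 2 h is to be read against -0.20. Quantile normalization moved that last median by 0.04.

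**Figure D1:**
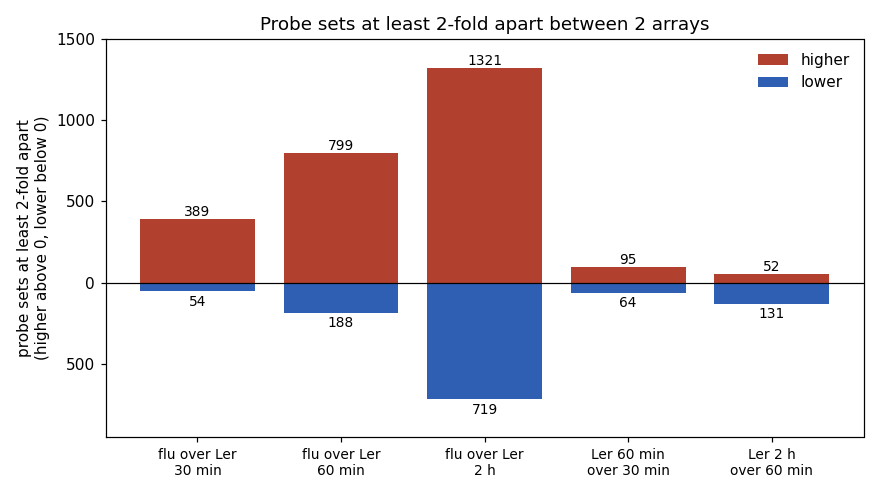
Number of probe sets (vertical axis, higher above 0 and lower below 0) at least 2-fold apart between pairs of arrays, for flu over Ler at each time and for neighbouring Ler times. At 2 h 1321 probe sets were higher and 719 lower in flu, against 52 and 131 between the Ler arrays of 60 min and 2 h.

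Genes such as STZ that stood at least 2-fold higher at 30 min were mostly so at the later times, on other arrays. Of the 389, 343 were also higher at 60 min, where independent lists would share 23.8, and 309 at 2 h, where they would share 39.3. Of the 54 lower at 30 min, 12 were also lower at 60 min (0.78 for independent lists) and 9 at 2 h (2.97). Of the 1321 probe sets higher at 2 h, 845 were less than 1.5-fold higher at 30 min, which is 64.0%, and AT2G29500 is among them. Of the 719 lower at 2 h, AT5G44680 among them, 658 were less than 1.5-fold lower at 30 min (91.5%).

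Gene lists fixed beforehand described which processes the differences fell in, with 58 of their genes tested. In these lists 9 genes were higher and 0 lower in flu, and 15 and 10 when the p-values were adjusted over these 58 genes alone, all lists together. Both tested genes of the list of singlet oxygen markers from earlier flu work were higher, AT3G01830 by 4.16 and FLOT3, of the flotillin family, by 3.23 (SE 0.27, adjusted p = 0.00247). That list was drawn from earlier work on the same mutant, so it is not independent evidence of a direction.

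In the list of calcium, MAP kinase and oxidase signalling, the 4 tested genes were all of the calmodulin-like family, and 3 of them were higher in flu. These were AT3G01830 (4.16), CML37 (3.99) and CML38 (3.59, SE 0.29, adjusted p = 0.00244). CML39 did not pass across the times (1.51, SE 0.89, adjusted p = 0.386), with differences of -0.18, 0.54 and 4.17 at the 3 times. The list median was 3.24 at 30 min, 3.31 at 60 min and 4.55 at 2 h, each above every one of 10000 random lists matched on mean expression. Those lists draw genes independently, while these 4 genes vary together (estimated correlation 0.92), so the ranks are a description and not a test. Camera with its preset correlation placed the list higher (adjusted p = 1.92e-06), but not with an estimated correlation (adjusted p = 0.258). Over all alternatives its adjusted p ranged from 8.64e-10 to 0.258.

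Among the 3 tested WRKY transcription factors, regulators of defence and senescence genes, WRKY53 was higher in flu by 2.82 (SE 0.24, adjusted p = 0.00289) and WRKY22 by 1.98 (SE 0.27, adjusted p = 0.0175). WRKY6 stood at 1.70 (SE 0.36, adjusted p = 0.0722) and did not pass. The list median was 1.79, 2.74 and 2.16 at the 3 times, and camera gave an adjusted p of 4.42e-05, or 0.258 with an estimated correlation. Of the 2 tested genes for salicylic acid and defence, SAG101, a lipase-like defence regulator, was higher by 1.52 (SE 0.21, adjusted p = 0.0173). The glutaredoxin GRX480 had 3.05 (SE 0.60, adjusted p = 0.0592), with 1.02 at 30 min and 4.31 at 2 h. The jasmonate biosynthesis list held OPCL1, which activates jasmonate precursors and was higher by 2.58 (SE 0.31, adjusted p = 0.0105), and JMT, which did not pass (0.61, SE 0.48, adjusted p = 0.513). ORA47, the only gene tested for jasmonate signalling and response, stood at 1.95 (SE 0.38, adjusted p = 0.0585). Of the zinc finger, DREB and NAC stress factors, STZ was higher in flu and ZAT5 had -0.68 (SE 0.17, adjusted p = 0.102).

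Photosynthesis genes of the nucleus lay on the low side in flu, though none of them passed the test across the 3 times over all probe sets. The 3 tested genes of the light-harvesting antenna, all for the minor antenna protein CP29, were LHCB4.3 (-1.19, SE 0.26, adjusted p = 0.0780), LHCB4.2 (-0.73, SE 0.23, adjusted p = 0.159) and LHCB4.1 (-0.42, SE 0.10, adjusted p = 0.0930), each negative at 3 of 3 times. Adjusted over the tested genes of all fixed lists together, all 3 passed. The median of this list was -0.44 at 30 min and -1.42 at 2 h, the latter at the 0.03 percentile of matched random lists. That rank is a description, since the random lists draw genes independently and these genes vary together (estimated correlation 0.40). All 6 tested genes of the photosystems and the Calvin cycle were likewise negative at each time, from PRK, phosphoribulokinase (-0.49, SE 0.10, adjusted p = 0.0558), to PSBW (-0.30, SE 0.11, adjusted p = 0.212). Adjusted over the genes of all fixed lists, 4 passed. Camera placed both lists lower (adjusted p = 0.0149 and 0.00185). With an estimated correlation neither did (adjusted p = 0.258 for both), and after quantile normalization the adjusted p were 0.0716 and 0.138 (ranges over all alternatives 0.00276 to 0.258 and 4.54e-05 to 0.258). Quantile normalization also moved the medians at 30 min, that of the antenna from -0.44 to -0.11 and that of the photosystems and Calvin cycle from -0.39 to -0.05, while at 2 h the antenna stood at -1.35 and the photosystems and Calvin cycle at -0.25, from -0.43. The median of the photosystems and Calvin cycle at 2 h lay at the 18.7 percentile of matched random lists, and that of the mean differences at 14.6.

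The tetrapyrrole pathway, which FLU regulates, had 8 tested genes, of which 0 passed. HEMA2, a glutamyl-tRNA reductase gene, stood at 1.62 (SE 0.33, adjusted p = 0.0653) with 2.51 at 2 h, while CHLI2, a magnesium chelatase subunit, had -0.71 (SE 0.17, adjusted p = 0.0903), HEME1 -0.48 and CHLM -0.46. PORB, protochlorophyllide oxidoreductase B, had -0.02, -0.38 and -0.84 at the 3 times. Adjusted over the tested genes of all fixed lists together, HEMA2 was higher and CHLI2 lower. The list median was 0.01 at 30 min and -0.80 at 2 h, at the 82.5 and 0.05 percentile of matched lists, and camera gave an adjusted p of 0.173, with a range over all alternatives of 0.0474, with the stricter filter, to 0.439.

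The other lists held fewer or smaller differences. The 4 genes that scavenge hydrogen peroxide and superoxide had a median of -0.41 (camera adjusted p = 0.0752, range over all alternatives 0.0230, without a filter, to 0.258), led by SAPX, stromal ascorbate peroxidase (-0.48, SE 0.15, adjusted p = 0.155). The 3 genes of the dark and starvation response had a mean-difference median of 0.34 (camera adjusted p = 0.0496, 0.258 with an estimated correlation). ATG8E among them stood at 0.76 (SE 0.20, adjusted p = 0.109), and the call was lost without any 1 time point (adjusted p from 0.0518 to 0.166), with a range over all alternatives of 0.0230 to 0.258. The 4 auxin response genes had a median of 0.32 (camera adjusted p = 0.0752), with GH3.3 at 0.91. Their list passed without a filter (adjusted p = 0.0418) and without the arrays of 2 h (adjusted p = 0.0194), in a range of up to 0.271. The 4 housekeeping genes had -0.06 (camera adjusted p = 0.878), from TIP41L at -0.15 to AP2M at 0.00. UPOX (3.67 at 2 h, -0.03 at 30 min) and NDB2 (2.91 and -0.17), both of mitochondrial alternative respiration, and the glutathione S-transferase gene GSTU25 (2.64 and -0.71) had late differences and did not pass across the 3 times. In a test of genotype by log2 minutes, chosen after the values had been seen, their differences rose with time (limma, adjusted p = 0.00808, 0.000720 and 0.0290). Over the alternatives of that test adjusted p ranged from 0.00337 to 0.0514 for UPOX, from 8.20e-05 to 0.0131 for NDB2 and from 0.0157 to 0.1004 for GSTU25. GSTU20 had a mean of -0.12. The remaining genes, none of which passed, were EIN3 of ethylene signalling (0.38), DFR (-0.47) and HYH (0.42) of the light response and flavonoid synthesis, GI of the circadian clock (-0.35), COR47 (0.23) and COR15A (0.19) of the abscisic acid and drought response, and FAMA of the guard cell, vascular and trichome markers (-0.07). No gene of the ERF, heat shock and flower, root and seed lists was tested.

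**Figure D2:**
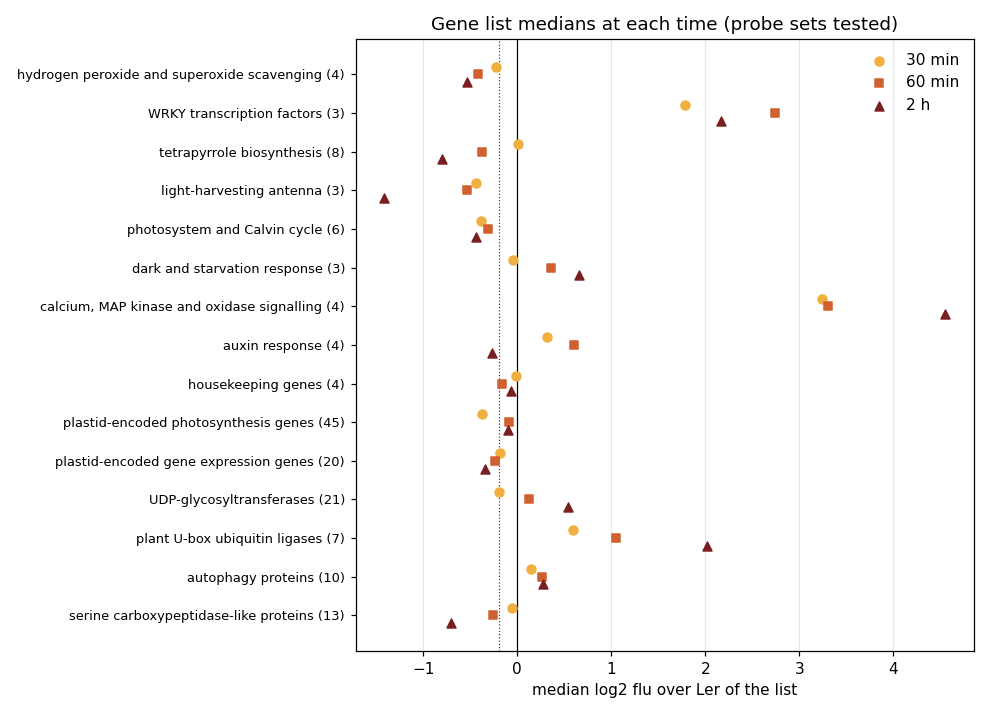
Median log2 flu over Ler (horizontal axis) of gene lists and gene families at the 3 times, with the number of probe sets tested in brackets and the median of all probe sets at 2 h as a dotted line. The calcium signalling list reaches 4.55 at 2 h, and the light-harvesting antenna list -1.42.

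How transcripts moved from 30 min to 2 h of light in both genotypes was the next comparison, and no probe set passed in it. The genes named here had the largest additive changes among single named genes at least 2-fold apart in both genotypes. AT5G48570 (ROF2), an immunophilin gene of the heat response, had 3.75 (adjusted p = 0.315), with 1.64 in Ler and 5.85 in flu. AT5G51440, for a small heat shock protein, had 3.33 (1.00 and 5.66). TBL26 (2.84), the DnaJ gene AT2G20560 (2.39), the Hsp70 gene AT3G09440 (2.17) and AT1G06000 (2.14) followed, and of these AT2G20560 was also higher in flu across the times (2.32, SE 0.39, adjusted p = 0.0342). The lowest were AT1G30250 (-2.62, adjusted p = 0.0997, with -2.69 in Ler and -2.55 in flu), RR16, a cytokinin response regulator (-1.86), AT4G27450 (-1.75), AT1G64380 (-1.75), AT3G23170 (-1.49) and COR27, a cold-regulated gene (-1.46). COR27 was also higher in flu across the times (1.51, SE 0.18, adjusted p = 0.00985).

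With limma, 0 probe sets passed for 2 h against 30 min and 0 for 60 min against 30 min, with smallest adjusted p of 0.0997 and 1.00. At an unadjusted p under 0.05 there were 1492 and 397. The residual of this fit also holds any change of the genotype difference with time, so a change shared by both genotypes can be missed. With the 75th percentile filter 4 probe sets passed for 2 h against 30 min, and without the arrays of 2 h 73 passed for 60 min against 30 min. At least 2-fold in both genotypes were 62 probe sets higher and 41 lower at 2 h, where independent lists would share 13.0 and 8.47. Across all probe sets the 2 h over 30 min changes in Ler and flu correlated with r = 0.126. Of the 9 lists tested as sets, camera placed only that of calcium, MAP kinase and oxidase signalling higher at 2 h (adjusted p = 0.0388, 0.791 with an estimated correlation). Its median was -0.11 in Ler and 1.54 in flu, and with an offset of 16, after quantile normalization or with a stricter filter the call was lost (adjusted p = 0.0901, 0.0532 and 0.355, with a range over all alternatives of 0.0240 to 0.791). Camera gave adjusted p between 0.523 and 0.718 for the other 8. For the photosystem and Calvin cycle genes the median (-0.04) and the direction of camera (higher) differed in sign.

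The difference between flu and Ler at 2 h was set against that at 30 min to see which genes responded late. AT2G29500 went from -0.43 to 5.78, AT2G41730 from -0.39 to 4.75, AT2G38240 from -0.89 to 4.25, the glucosyltransferase gene UGT73B5 from -0.20 to 4.75 and AT1G66850 from -1.20 to 3.65. In the opposite sense AT5G61590 (DEWAX), a repressor of wax biosynthesis, went from 1.22 to -1.72, AT5G44680 from 0.08 to -2.83, AT1G23030 from 0.66 to -2.11 and AT1G54820 from 0.24 to -2.46, with AT1G13650 the last of the named genes. UGT73B5 had a Ler signal of 4.8 at 2 h, near background, so that the size of its difference there is left to the offset (6.11 with an offset of 16 and 3.86 with 100). The 30 min signals of AT1G66850 were dim, 16.1 in flu and 102 in Ler, and with an offset of 100 its difference there was -0.80. AT2G38240 had signals of 64.4, 158 and 3972 in flu and of 162, 178 and 162 in Ler. In all, the signed log2 difference of flu over Ler rose by 2-fold or more from 30 min to 2 h for 1113 probe sets and fell by as much for 833. A fall includes differences that became more negative, such as that of AT5G44680. A test of genotype by log2 minutes, with time as a factor, was chosen after these values had been seen. In it the difference rose with time for 476 probe sets and fell for 188 (limma, adjusted p under 0.05), the 10 genes named here among them (adjusted p from 0.000288 to 0.00630), and 1235 and 1236 had an unadjusted p under 0.05. The 10 genes had been picked for their change on these same arrays. The test has 1 residual degree of freedom beside 9.65 from the prior, so its error is mostly borrowed from other probe sets. After quantile normalization 290 rose and 89 fell, and without a variance trend 280 and 58. Of the 10 genes only AT1G66850 lost its call under an alternative, with the stricter filter (adjusted p = 0.0615, with a range over its alternatives of 0.00189 to 0.0615).

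**Figure D3:**
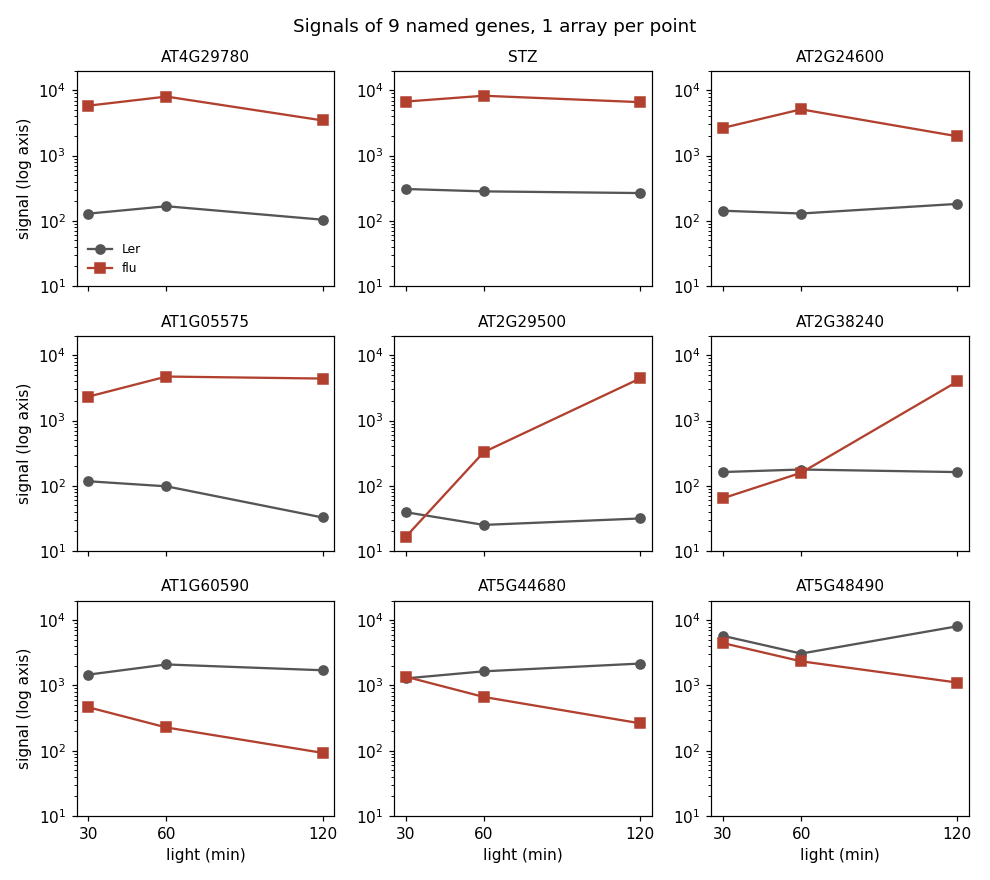
Signals (vertical log axis) of 9 named genes against minutes of light (horizontal axis) in Ler (grey circles) and flu (red squares), 1 array per point. STZ lies between 6607 and 8279 in flu at all 3 times, AT2G29500 climbs from 16.4 to 4419 in flu, and AT1G60590 lies at 92.5 in flu at 2 h against 1711 in Ler.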

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

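Of the tests in this part, those on quantile normalization and on other splits of the arrays were chosen before their results were seen, and those on the share at 2 h, on plastid genes, on the values at 60 min and on the change with time, with its alternatives, only after. Each group had 1 array, so no array could be compared with replicates of its group.

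Of 130 reported probe sets, the difference between flu and Ler changed with time in 40 (limma, genotype by log2 minutes, adjusted p from 0.000288 to 0.0499). These p-values set the slope over log2 minutes against an error that is mostly borrowed from other probe sets (9.65 prior degrees of freedom). The probe set's own part of that error has 1 degree of freedom, its departure from a straight line. It is not a spread over replicates. A deviation of the arrays of 30 min or 2 h would enter the change itself. Some of the 130 were named for a large change on these same arrays. The sizes below are log2 changes per doubling of the minutes of light. From the largest down, they were 3.10 for AT2G29500, 2.57 for AT2G41730, 2.57 for AT2G38240, 2.47 for UGT73B5, 2.43 for AT1G66850, 2.33 for AT5G51440, 2.24 for Hop3, 2.17 for CML39 (AT1G76640), 2.11 for AT5G48570 and 2.04 for Fes1A. UPOX (AT2G21640) had 1.85, PUB19 1.84, GSTU25 1.67, GRX480 1.65, NDB2 1.54, AT4G39670 1.49, AT2G20560 1.07, Hsp70-2 0.995, CML37 0.96, AT1G05575 0.96, XTH18 0.92, OPCL1 0.83, BZIP60 0.66 and AT3G09440 0.60. The plastid gene psbA had 1.61 and AT3G48460 0.66, both with negative differences at 30 min. Negative changes were those of BZIP61 (-1.54), AT5G61590 (-1.47), AT5G44680 (-1.45), AT1G23030 (-1.39), AT1G54820 (-1.35), AT1G13650 (-1.31), EXPA8 (-1.27), AT5G48490 (-1.22), AT1G60590 (-1.03), AT1G23205 (-1.002), GSTU27 (-0.88), AT1G35210 (-0.84), AT2G47440 (-0.70) and LHCB4.2 (-0.59). The order of the largest depends on the offset, since with an offset of 16 UGT73B5 had 3.21, Hop3 3.00 and AT2G41730 2.69. Under the other offsets, scalings, filters and variance prior, all 40 kept their sign where they were tested and 23 passed throughout. Calls were lost most often without a variance trend (28 of 40 passed) and after quantile normalization (31 of 40). The 17 that lost their call under at least 1 alternative are Hop3, AT2G20560, AT3G09440, CML39, CML37, UPOX, GSTU25, GSTU27, AT1G66850, XTH18, OPCL1, BZIP60, AT3G48460, AT5G48490, AT1G35210, AT2G47440 and LHCB4.2. Of the 10 splits of the arrays this test could be fitted to 4, of which the real one gave 664 probe sets and the highest of the others 0, too few splits for a share under 0.05.

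UGT76E11, a glucosyltransferase gene, went from -1.03 at 60 min to 1.21 at 2 h, a change of 2.24 that was not tested between these times, and its change per doubling did not pass (0.87, adjusted p = 0.151). AT1G66850 and AT5G61590 also lay at least 2-fold apart in opposite directions, from -1.20 to 3.65 and from 1.22 to -1.72. For AT1G66850 this rests on dim signals at 30 min (16.1 and 102), where an offset of 100 gave -0.80.

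Of 19 control probe sets for Arabidopsis genes, which no comparison used, 1 was at least 2-fold above Ler. The probe set for the middle of a ubiquitin transcript (AFFX-Athal-Ubq_M_f_at) had a signal of 7844 in flu against 3485 in Ler at 2 h, a log2 difference of 1.16, after 0.88 at 60 min and -0.04 at 30 min. The ubiquitin probe sets for the 3' end and the 5' end of the same set had 0.56 and 0.68 at 2 h. Those of a second ubiquitin set on the array (AFFX-r2-At-Ubq) had smaller differences, 0.07 and 0.45.

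The excess of higher over lower probe sets in flu across the 3 times (88.4% of 424) was weighed first. The choice between 2 scalings does not account for it: after quantile normalization 88.4% were higher again, and 407 of the 424 probe sets passed under both. Quantile normalization moved no log2 value by more than 0.334, and both scalings give the arrays a like overall signal. An error that both scalings share therefore cannot be decided by this test. The test counts growing responses as noise, which may have kept lower probe sets out. At 2 h alone 64.8% of the probe sets at least 2-fold apart were higher, a value between the bounds set for and against this explanation. Of those lower at 2 h 91.5% were less than 1.5-fold lower at 30 min, and of those higher 64.0% less than 1.5-fold higher. On simulated data the fit recovered 0% of changes that grew with time. At an unadjusted p under 0.05 (limma) 1203 were higher and 1464 lower, beside medians of all probe sets of -0.04, -0.08 and -0.20. The excess is thus not one of all differences, large and small. Among large differences it was there without a test, with 301 higher and 6 lower by at least 2-fold at all 3 times. At 30 min alone, a count that no residual enters, 389 were higher and 54 lower by as much (87.8% higher, 67.8% without a filter). How much of the excess the counting of growing responses as noise makes up was not tested. Of the 10 splits of the 6 arrays into 3 and 3, 1 (the real one) gave 424 probe sets past the threshold, and the highest of the others gave 0, but only 3 of the others have 1 array of each time on each side, and no share under 0.05 can be reached. The genotype is the biological difference that the design names.

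The plastid-encoded photosynthesis genes had a median log2 difference of -0.37 at 30 min, with 41 of 45 below 0, and of -0.08 and -0.10 at 60 min and 2 h, the last being 0.04 after quantile normalization. Compression of bright signals on that flu array may make up part of this, as random nuclear lists matched on the Ler signal had a median of -0.18. Quantile normalization left -0.14 of the -0.37. Of 10000 matched lists 0% had a median as low. The lists draw genes independently, while these plastid genes vary together (estimated correlation 0.33). The 0% therefore cannot decide whether compression is the whole cause. The SD of the differences over 65 plastid-encoded genes was 1.303 times that at 60 min (0.41 against 0.32), as predicted for an even loss of plastid RNA from this array. Without psbA, at -2.42, the SD at 30 min was 0.322. An SD does not register a shift shared by all genes and could be as small without any loss, so it cannot decide this explanation. Whether both plastid gene families were lost alike stays open, as the medians of the photosynthesis and gene expression genes differed by -0.19 (permutation test over genes, two-sided, p = 0.0314), but by -0.03 after quantile normalization (p = 0.694). That array stood apart in other measures as well. Its hybridisation controls had a geometric mean signal of 532, against 781 to 1217 on the others, and its maximum signal of 20372 was the lowest (21156 to 31005 on the others). Its ratio of the 3' to the 5' actin probe set was the highest at 2.08 (1.31 to 2.03 on the others), while that of GAPDH was the lowest at 0.834 and that of ubiquitin within the range of the others at 1.304. An effect of this 1 array on plastid photosynthesis probe sets, psbA included, stays open beside the genotype.

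The larger number of probe sets at least 2-fold apart at 2 h (2040) than at 30 min (443) was weighed last. If the arrays of 2 h deviated by themselves, the same probe sets would show no difference at 60 min, yet their median there was 0.76 in the direction of 2 h, against 0.20 at 30 min. This argues against the arrays of 2 h as the whole cause, but not as a part of it. Of the 1321 probe sets higher at 2 h, 430 were less than 1.5-fold higher at both 30 and 60 min. The choice between the 2 scalings is argued against too, since the count at 2 h was 4.43 times that at 30 min after quantile normalization and 4.61 times without it. An error that both scalings share was not tested. No array effect that grows steadily with time was tested, and the genotype stays a candidate explanation.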

How the results depend on the processing

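With 1 array per genotype and time, no call could be checked against replicates, and a dim signal over background limits what a difference shows. Of the alternatives, those run on the families defined by symbol were chosen after seeing the annotation, and the test of the change with time and its alternatives after seeing the data. No reported difference past the threshold changed sign under any alternative, and the deposited values without rescaling changed nothing of note, since they had been scaled before. The change versus 30 min could not be fitted without the arrays of 30 min. The lower probe sets depended most on the setting. Past the threshold across the 3 times there were 49, and 14 without a filter, 77 with the 75th percentile filter, 15 without a variance trend, 131 without time in the fit and 18 with a mean change of at least 2-fold. At 30 min 54 were at least 2-fold lower, and 116 with an offset of 16, 25 with an offset of 100, 216 without a filter and 27 with the stricter filter, which also gave 465 at 2 h, 471 whose difference fell from 30 min to 2 h, 4 probe sets for 2 h against 30 min and 2 added families lower at 2 h. At least 3-fold apart were 213 higher and 4 lower at 30 min, 440 and 27 at 60 min, and 825 and 137 at 2 h, as a stricter size must give. From 30 min to 2 h the signed log2 difference of flu over Ler rose by 2-fold or more for 1113 probe sets and fell by as much for 833. A test of genotype by log2 minutes gave 476 and 188, or 290 and 89 after quantile normalization and 280 and 58 without a variance trend. That test could not be fitted with a time left out. Leaving out each time in turn gave 75 to 595 higher and 0 to 134 lower probe sets, 1 to 4 added families lower, and 73 for 60 min against 30 min without 2 h. Of the lists, 3 were higher and 2 lower in flu and 1 was higher at 2 h. After quantile normalization 0 were lower and 0 higher at 2 h, with an offset of 16 and with the stricter filter 0 were higher at 2 h, and with fry or an estimated correlation 0 lists and 0 added families passed in any direction. Calls were also gained in flu against Ler, by the peroxide scavenging list without a filter (adjusted p = 0.0230), the auxin list without a filter or without 2 h (adjusted p = 0.0418 and 0.0194) and the tetrapyrrole list with the stricter filter (adjusted p = 0.0474), and by the families of bZIP factors, serine carboxypeptidase-like proteins and organelle RNA editing factors. Where fewer probe sets or arrays do not explain it, the cause was not tested.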

Other observations

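The families in this part were defined by gene symbol after the annotation had been seen, and before any difference was computed, while the genes named from them were chosen after their values were seen. Of 7 ubiquitin ligases of the plant U-box family 1 passed. PUB23, a negative regulator of immune signalling, was higher in flu by 2.98 (SE 0.37, adjusted p = 0.0121), with 4.09 at 60 min. PUB24 (1.73, SE 0.36, adjusted p = 0.0673), PUB22 (1.18) and PUB19 (1.51, with 3.40 at 2 h) did not pass across the times. The median of the 7 tested genes was 0.59, 1.05 and 2.02 at the 3 times (limma's camera, adjusted p = 5.44e-05, or 0.446 with an estimated correlation). Of 9 bZIP factors, BZIP60 and BZIP28, membrane-bound factors of the unfolded protein response, were higher by 2.24 (SE 0.27, adjusted p = 0.0106) and 1.17 (SE 0.17, adjusted p = 0.0198), while BZIP61 had 0.69 at 30 min and -2.39 at 2 h. Of 6 tetraspanins, TET8 was higher by 1.78 (SE 0.12, adjusted p = 0.00143), with 1.73, 1.78 and 1.83 at the 3 times. The 10 autophagy genes had a median of 0.16 (camera adjusted p = 0.0180, or 0.630 with an estimated correlation), and ATG8H reached 1.86 at 2 h.

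Of 21 UDP-glycosyltransferases 0 passed the test over the 3 times. At 2 h 8 of them were at least 2-fold higher, as were 10.1% of all probe sets, UGT73B5 (4.75), UGT76E12 (4.33), UGT73B4 (2.37) and UGT73C1 (2.32) among them, after -0.20, -0.03, -0.40 and -0.55 at 30 min, each over a Ler signal near background at 2 h (4.8, 5.3, 9.0 and 14.3). UGT88A1 was at least 2-fold lower (-1.24), and the family median at 2 h was 0.545. Camera gave the family an adjusted p of 0.311. In the test of genotype by log2 minutes (limma) UGT73B5 passed (adjusted p = 0.000905). UGT76E12, UGT73B4 and UGT73C1 did not (adjusted p = 0.0547, 0.197 and 0.117). UGT87A2 and UGT84A3, which are not among the 130 reported probe sets, passed with smaller changes per doubling of minutes (1.15 and 0.89, adjusted p = 0.00893 and 0.0217). Of 14 chaperones and co-chaperones, 4 were at least 2-fold higher at 2 h, Hop3 at 3.90, Fes1A at 3.75, Hsp70-2 at 2.13 and Fes1B at 1.71, after -0.58, -0.32, 0.14 and 0.55 at 30 min. Cpn60beta4 was at least 2-fold lower (-1.18), and the median of the 14 was -0.27 at 30 min and 0.14 at 2 h. Hop3 had a Ler signal of 21.6 at 2 h, so its value depends on the offset. In the plastid genome rpl14, for a ribosomal protein, was lower in flu (-0.82, SE 0.14, adjusted p = 0.0414), the only 1 of 65 plastid-encoded genes tested that passed. The 20 plastid-encoded gene expression genes had a median of -0.24 and the 45 photosynthesis genes -0.20 (camera adjusted p = 0.00309 for both, 0.630 and 0.706 with an estimated correlation). Against random lists matched on mean expression these medians lay at the 21.4 and 53.7 percentile, and the photosynthesis genes lay at 0 at 30 min, 88.5 at 60 min and 99.8 at 2 h. After quantile normalization the adjusted p of the photosynthesis genes was 0.637 and without 30 min 0.510, with a range over all alternatives of 6.28e-05 to 0.706. EX1, which encodes the plastid protein EXECUTER1 that relays singlet oxygen responses, had -0.22 (SE 0.17, adjusted p = 0.491).

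The other families were tested with camera as well. The calmodulin-like proteins (median 1.27, adjusted p = 3.04e-05) and the named WRKY factors (1.70, adjusted p = 0.00636) overlap with the lists above, and with an estimated correlation their adjusted p were 0.446 and 0.630. The serine carboxypeptidase-like proteins had -0.37 (adjusted p = 0.0512), the organelle RNA editing and chlororespiratory reduction factors -0.58 (adjusted p = 0.0589) and the SWEET sugar transporters -0.26 (adjusted p = 0.124). Of these the serine carboxypeptidase-like proteins passed after quantile normalization (adjusted p = 0.0406) and without 60 min (adjusted p = 0.0275), in a range of up to 0.706, and the organelle factors without 60 min (adjusted p = 0.0275, range up to 0.706). For the bZIP factors the median was -0.06 and the direction of camera higher (adjusted p = 0.0905, or 0.00998 with the stricter filter and 0.0194 without 2 h, range up to 0.630). Adjusted p lay between 0.477 and 0.978 for the tau class glutathione S-transferases, beta-glucosidases, expansins, xyloglucan endotransglucosylases, tetraspanins, trichome birefringence-like proteins, CYP71B cytochromes P450 and chaperones. Among these the median and the mean or camera's direction differed in sign for the glutathione S-transferases, beta-glucosidases, xyloglucan endotransglucosylases, tetraspanins and CYP71B cytochromes P450. From 30 min to 2 h over both genotypes, camera placed 4 families higher, the plastid-encoded photosynthesis and gene expression genes (adjusted p = 0.00149 for both), the chaperones (adjusted p = 0.00259) and the UDP-glycosyltransferases (adjusted p = 0.00975). With an estimated correlation none of the 4 was (adjusted p from 0.756 to 0.800). The medians of the 4 in Ler were -0.02, 0.23, 0.19 and -0.04, and in flu 0.20, 0.08, 0.59 and 0.41, so for the photosynthesis genes and the UDP-glycosyltransferases the median in Ler did not point the same way. For this change the CYP71B cytochromes P450 passed as higher without a filter (adjusted p = 0.0341, range up to 0.828), and the expansins and tetraspanins as lower with the stricter filter (adjusted p = 0.0437 and 0.0435, ranges up to 0.778 and 0.756). At 2 h EXPA8, an expansin, had -2.46, and GSTU27 had -1.83.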
